A study of Mus musculus with 9 samples.

How the data were processed

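Gene expression was measured with Affymetrix whole-transcript microarrays in bone marrow from 15 mice, hybridised as 9 samples on 9 arrays. Per the labels' protocols, marrow was taken from the femur of C57BL6 mice, RNA was extracted with TRIzol and cleaned with phenol and chloroform, and biotin labelling followed the Affymetrix whole-transcript kit. Each array holds 28853 probe sets, and a probe set is a group of short probes on the array that read the same transcript region. The deposited values are intensity values on a linear scale, made by the authors with RMA (robust multi-array averaging, which corrects background, normalizes the arrays together and summarises the probes of a probe set) in Partek, per the submitters' processing notes. The versions of both, the genome build and the probe sequences are not given in the sources used here, so no coordinates are printed. The design, fixed before the data were examined, assumed log2 values. The values proved to be linear, so they were log2-transformed first, and no further normalization was applied.

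Names were taken only from the platform's annotation table, with symbols updated through Entrez identifiers. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 were not named. Only those with 1 symbol entered the tests. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays stood for the gene, which left 19938 genes. Of these, 19856 were found by Entrez identifier in a RefSeq gene table of the assembly GRCm38.p6, used for names alone. No filter was set on dim genes. The median intensity of all probe sets was 33.4, and 55.2% of genes had a group mean above it. Where the lower group mean lies below that median, the size of a change is limited by background and is read as a lower bound. The number of arrays, 3 per group, limits the precision of every value.

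Samples were grouped by the submitters' titles and source names into wild type whole marrow, wild type lineage-negative marrow and ERG leukemia marrow, with 3 arrays each. Replicate numbers of the wild type groups follow the titles, and the leukemias were numbered 1 to 3 in accession order, which pairs them with nothing. The wild type groups came from different mice. Per the submitters' design notes, the leukemias came from 3 transgenic mice, and the titles of 2 of them differ by 1 final digit. Each whole marrow or leukemia array stands for 1 mouse and each lineage-negative array for a pool of 3 mice. The p-values rest on 1 spread per gene shared by the 3 groups, so they do not measure the spread between mice alone. The pools spread less, with a median standard deviation of 0.101 over genes, against 0.127 in each other group.

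All 3 pairwise comparisons were made in 1 linear model of the 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend), which had 6 residual and 2.62 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and the threshold was an adjusted p of 0.05. Values are given as a log2 difference ± its standard error, as a fold of the group means of log2 values, or as mean intensity, and SD is the standard deviation over 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

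Before the data were examined, the samples' groups, the tests, the alternatives, the rule for naming genes and 23 gene lists were fixed. The lists covered the 7 blood stem cell factors known as the heptad, stem and progenitor cells, erythroid cells, heme synthesis, megakaryocytes and platelets, primary granules and promyelocytes, secondary granules and mature neutrophils, monocytes with macrophages and dendritic cells, eosinophils with basophils and mast cells, B cells, T and NK cells, plasma cells, stroma with bone and endothelium, DNA replication, mitosis, ribosome biogenesis with MYC targets, p53 targets, kinase and survival oncogenes, MAPK feedback genes, immediate early and stress genes, type I interferon targets, cholesterol synthesis and glycolysis. Of 529 listed symbols, 472 were measured and 57 were not. The kinase and survival oncogene list was drawn up with genes remembered from work on these mice and is not independent of the study. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 23 lists of a comparison. Alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move, on balance, one way. A count adjusted over the list alone applies the Benjamini-Hochberg method to the members of that list.

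For each comparison the rule named Erg, Pim1, the 6 genes with the highest and the 6 with the lowest log2 difference among those past the threshold whose 3 arrays in one group all lay above the 3 of the other, and the 2 members of each list with the largest change past the threshold. Clone names, predicted genes, olfactory receptors and antigen receptor segments were passed over. The heptad was named in full for the leukemia. Members named beyond this rule, where a list had 5 or fewer on a side and for genes outside both references, were chosen after their values were seen. Enrichment of lists among genes outside both references was tested with Fisher's exact test against all 19938 genes, adjusted over the 23 lists, and that test was added after the data were examined.

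The alternatives were cyclic loess between the arrays, centring each array on its 75th percentile, only genes above the median of all probe sets (11001 genes), eBayes with trend and robust, array weights, the mean of a gene's probe sets, all probe sets separately, a log2 size of at least 1, only the 2 groups compared, the replicate number as a block for the wild type groups, and leaving out each array in turn. For comparisons that share arrays, 20 data sets with no group differences were simulated. The fit was tested on simulated data in which 200 of 19938 genes were changed and the DNA replication list was raised as well. Of genes changed by 1 on the log2 scale it recovered 82.1% for leukemia against whole marrow, 80.6% for leukemia against lineage-negative marrow and 89.6% for lineage-negative against whole marrow. Of genes changed by 0.5 it recovered 43.3%, 29.9% and 35.8% in that order, and false calls made up 3.8%, 2% and 7.4% of all calls. Fewer genes were changed there than were called in any real comparison. The simulated noise was also drawn apart for each gene, while real genes vary together. Recovery and false calls in the real comparisons may therefore differ.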

Results

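The arrays measured RNA from the bone marrow of wild type mice and of mice that carried an ERG transgene and had developed a myeloid leukemia. ERG is a transcription factor of the ETS family that blood stem cells need. Marrow of 3 wild type mice was used whole, and marrow of 9 others was lineage-depleted, a step that removes cells bearing mature blood cell markers with antibodies and magnets, and pooled into 3 samples of 3 mice. Marrow of 3 transgenic mice was collected whole once signs of leukemia appeared. The median intensity per array ran from 32.3 to 34.4, and arrays of the same group correlated across genes at r between 0.971 and 0.995. The first principal component held 62% of the variance and placed the leukemias, at -0.2 to 25.3, between whole marrow, at -59.3 to -48.9, and lineage-negative marrow, at 36.5 to 58.1. The second, with 18.4%, parted the leukemias, at -38.5 to -25.3, from all wild type arrays, at 5.4 to 29.1.

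The mouse Erg gene was read by 1 probe set, and its signal was lower in the arrays labelled ERG transgenic. Mean log2 intensity of Erg was 6.37 ± 0.21 (SD) in the leukemias, 6.80 ± 0.23 in lineage-negative marrow and 7.29 ± 0.30 in whole marrow. The labels do not state the species of the transgene, so this probe set checks nothing about the transgene itself. Sex-linked genes also differed between arrays. Xist, the RNA that silences an X chromosome in females, stood at a log2 intensity of 4.32 in whole marrow array 2 and between 8.80 and 11.11 on every other array. The Y-linked gene Eif2s3y stood at 8.53 in whole marrow array 2 and at 7.89 to 8.23 in the lineage-negative pools, against 3.98 to 4.18 in the leukemias and in whole marrow arrays 1 and 3 at 4.06 and 4.09. The lineage-negative pools thus carried signal of both genes, and the sex of the mice is not in the labels.

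Set against wild type whole marrow, the tissue in which the leukemia grew, leukemic marrow had higher signal of ribosome biogenesis, DNA replication, erythroid and heme synthesis genes. It had lower signal of B cell, mature neutrophil, eosinophil and basophil, T and NK cell and interferon-induced genes. All 29 measured ribosome biogenesis genes and 18 of 22 erythroid genes rose, while 21 of 25 B cell genes and 16 of 23 mature neutrophil genes fell. The stem and progenitor cell factor Gata2 rose 8.76-fold, from a mean intensity of 115.8 to 1013.9, and Igll1, part of the pre-B cell receptor, was at least 12.9-fold lower, with a leukemia mean of 23.3 that lies below the median intensity of 33.4. By limma, 2901 of 19938 genes were higher and 1980 lower in the leukemias, 24.5% of the genes. Of all genes tested, 37.1% had groups whose arrays did not overlap, against 10% by chance. The share of calls that were higher was 59.4% with the deposited values, 47.7% with each array centred on its 75th percentile (2215 higher and 2431 lower) and 47.2% after cyclic loess (2174 and 2428), and it was 43.7% at a log2 size of at least 1. Without whole marrow array 1, 1248 genes were lower.

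The largest rises included enzyme, junction and surface protein genes. Cda, which encodes cytidine deaminase, rose from a mean intensity of 21.3 to 442.3 (log2 difference 4.37 ± 0.96, limma adjusted p = 0.0113). Clca3a1 rose by 4.23 ± 0.31 (adjusted p = 0.000398) and Tjp1, a tight junction protein gene, by 3.93 ± 0.49 (adjusted p = 0.00128). Plek2 and Bex4 rose at least 12.8-fold and 12.7-fold, and the complement inhibitor gene Cd59a rose 12.2-fold, from 109.1 to 1332.3. In whole marrow Cda, Tjp1, Plek2 and Bex4 lay below the median intensity of 33.4, as Ebf1, Igll1 and Vpreb3 did in the leukemias, so the sizes of these changes are lower bounds. Among the named genes the largest fall as measured was that of Ppbp, a platelet chemokine gene, from 1968.3 to 124.2 (-3.99 ± 0.51, adjusted p = 0.00138). The falls of Ebf1, Igll1 and Vpreb3 may be larger. Ebf1, the transcription factor that sets B cell identity, changed by -3.83 ± 0.54 (adjusted p = 0.00194). Igll1, of the pre-B cell receptor, changed by -3.69 ± 0.44 and Vpreb3, another gene of the B cell list, by -3.54 ± 0.47. Mirt2 was 11.3-fold lower. H2-Ea, an MHC class II gene, changed by -3.38 ± 0.96 (adjusted p = 0.0328), with log2 values of 4.55, 8.23 and 4.64 in leukemias 1, 2 and 3. Its call was lost without leukemia 1 (-2.75) or 3 (-2.80), whole marrow array 1 (-3.41) or 3 (-2.87) or lineage-negative pool 3 (-3.38), and with only the 2 groups compared. H2-Ab1, another MHC class II gene, chosen after its values were seen, ran the other way, at 8.43, 6.12 and 8.18 in leukemias 1, 2 and 3. The labels name 1 strain, C57BL6, and differences in genetic background between the mice were not tested. The H2-Ea fall is therefore not read as an effect of the leukemia. Each gene that the rule names past the threshold in any comparison had all 3 arrays of one group above all 3 of the other, except Pim1 against whole marrow.

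Erythroid genes rose as a group in the leukemias. Of 22 measured members 18 rose, 0 fell and 4 did not pass (19 rose when adjusted over the list alone), with a median log2 difference of 1.67. Gata1, the master regulator of erythroid and megakaryocyte genes, rose 5.05-fold (2.34 ± 0.45, limma adjusted p = 0.00655), and Epb42, which encodes a red cell membrane skeleton protein, rose 4.63-fold (2.21 ± 0.45). Against other genes the list was higher by camera at the preset correlation (adjusted p = 3.52e-10), with adjusted p = 0.354 with an estimated correlation. Heme synthesis followed, with 6 of 11 genes up, 0 down and 5 not passing (9 up when adjusted over the list alone). Cpox, a heme pathway oxidase gene, rose 5.93-fold and the mitochondrial transporter gene Abcb10 rose 3.7-fold. For heme synthesis camera gave an adjusted p of 3.93e-05, and adjusted p = 0.373 with an estimated correlation.

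Genes of growth and division were higher in leukemic than in whole marrow. In the DNA replication list 26 of 31 members rose and 0 fell (27 rose when adjusted over the list alone), with a median of 0.58. The thymidine kinase gene Tk1 rose by 1.01 ± 0.14 and Pole, the catalytic subunit of DNA polymerase epsilon, by 1.00 ± 0.14 (limma adjusted p = 0.00162 for each). The ribosome biogenesis and MYC target list rose in 29 of 29 members with a median of 1.01, also when adjusted over the list alone. Rrp9, which works in ribosomal RNA processing, rose 3.01-fold and Cad, the enzyme that opens pyrimidine synthesis, 2.96-fold. By camera the adjusted p was 5.81e-13 for DNA replication and 4.51e-19 for ribosome biogenesis, and for each adjusted p = 0.303 with an estimated correlation. In the mitosis list 19 of 30 genes rose and 1, Kif23, fell (25 and 1 when adjusted over the list alone), with Nek2 at 0.81 ± 0.11 and Cdc20 at 0.80 ± 0.13. The mitosis count depended on scaling and on 1 array, with 6 up after cyclic loess, 9 with 75th percentile centring and 12 without whole marrow array 1, and Kif23 was lost without leukemia 1 or 2 (camera adjusted p = 9.1e-10, and adjusted p = 0.303 with an estimated correlation). Of 16 cholesterol synthesis genes 7 rose and 0 fell (9 and 0 when adjusted over the list alone), led by Sqle (1.52 ± 0.17) and Fdft1 (1.29 ± 0.21). For cholesterol synthesis camera's adjusted p was 0.000344, with adjusted p = 0.354 with an estimated correlation. The cholesterol count was 4 under both scalings and without whole marrow array 1 or 3, lineage-negative pool 3 or leukemia 2.

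Most mature neutrophil genes and most eosinophil, basophil and mast cell genes were lower in the leukemias than in whole marrow. In the mature neutrophil list 16 of 23 genes fell and 0 rose (18 fell when adjusted over the list alone), with a median of -1.56. Csf3r, the receptor for granulocyte colony-stimulating factor, was 5.87-fold lower (limma adjusted p = 0.00217) and Ptgs2 5.35-fold lower (adjusted p = 0.00187). Of 13 primary granule genes 6 fell and 0 rose (9 fell when adjusted over the list alone), including Csf3r, which both lists hold, and Hdc, the histamine-forming enzyme, at -2.38 ± 0.35. For mature neutrophils camera's adjusted p was 1.8e-09, with adjusted p = 0.354 with an estimated correlation, and for primary granules it was 0.000282, with adjusted p = 0.373 with an estimated correlation. Without whole marrow array 1 the mature neutrophil count was 10, and the primary granule count was 3 without whole marrow array 1 or 2 or leukemia 2. Of 19 eosinophil, basophil and mast cell genes 11 fell and 0 rose (14 fell when adjusted over the list alone), with a median of -1.28. The basophil protease gene Mcpt8 fell most (-2.66 ± 0.48, adjusted p = 0.00495), followed by Hdc. Camera gave that list an adjusted p of 1.87e-07, and adjusted p = 0.303 with an estimated correlation.

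Lymphoid and interferon-induced genes were also lower. B cell genes fell in 21 of 25 cases and rose in 0 (22 fell when adjusted over the list alone), with a median of -2.11 and with Ebf1 and Igll1, described above, in the lead. For the B cell list camera's adjusted p was 5.63e-11, and adjusted p = 0.354 with an estimated correlation. In the T and NK cell list 17 of 28 genes fell and 1 rose (24 and 1 when adjusted over the list alone), and 11 fell without whole marrow array 1. The T cell receptor subunit gene Cd3e changed by -1.34 ± 0.24 (limma adjusted p = 0.00458). The member that rose was Lat (2.00 ± 0.35, adjusted p = 0.00429), a signalling adaptor that T cells share with mast cells and megakaryocytes. Type I interferon targets fell in 13 of 22 cases and rose in 0 (17 fell when adjusted over the list alone), with Rtp4 at -2.23 ± 0.28 and Oas2, a sensor of double-stranded RNA, at -2.12 ± 0.31. Against other genes camera's adjusted p was 1.45e-08 for T and NK cells and 1.11e-06 for interferon targets, and for each adjusted p = 0.303 with an estimated correlation. Of 22 immediate early and stress genes 7 fell and 0 rose (10 fell when adjusted over the list alone), with Btg2 2.4-fold and Zfp36 2.13-fold lower (camera adjusted p = 0.00242, and adjusted p = 0.373 with an estimated correlation). The Zfp36 call was lost without leukemia 3 (-0.89) or whole marrow array 1 (-1.015), and 2 members of the list rose without leukemia 3. In the leukemias Fosb and Jun, chosen after their values were seen, stood at 7.95, 8.55 and 4.82 and at 8.83, 7.99 and 5.91 in leukemias 1, 2 and 3.

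The heptad, a set of transcription factors that work together in blood stem cells and to which ERG itself belongs, split. Gata2 (3.13 ± 0.32, limma adjusted p = 0.000696), Tal1 (3.02-fold, adjusted p = 0.00212) and Lmo2 (1.16 ± 0.12, adjusted p = 0.000723) rose, while Erg (-0.91 ± 0.18, adjusted p = 0.00739) and Fli1 (-1.69 ± 0.37, adjusted p = 0.0114) fell. Runx1 (-0.08 ± 0.17, adjusted p = 0.812) and Lyl1 (0.17 ± 0.09, adjusted p = 0.215) did not pass. The counts adjusted over the list alone were also 3 up and 2 down, and the list median of 0.165 turned to -0.021 after cyclic loess. For the heptad camera's adjusted p was 0.207, with 0.373 with an estimated correlation, while fry's was 0.00269 (up). Stem and progenitor genes went both ways, with Bcl11a, Slamf1, Cdk6 and Egfl7 up and Cd34, Sox4, Procr, Prom1 and Satb1 down among 27 measured (4 up and 7 down when adjusted over the list alone). Slamf1, a marker of blood stem cells and megakaryocyte progenitors, rose 9.02-fold and Satb1, a lymphoid chromatin factor, was 4.43-fold lower. The camera p of 0.102 for this list became 0.0267 without whole marrow array 2 and 0.0239 without leukemia 1. Its counts were 2 up and 3 down without whole marrow array 1 or 3, 3 down without leukemia 2 or 3, 8 down without lineage-negative pool 2, and 2 up and 8 down with 75th percentile centring. Megakaryocyte and platelet genes also split, with Gp5, F2r, Gfi1b, Zfpm1 and Rab27b up and Ppbp, Itgb3, Gp9 and Cd9 down among 20 measured (7 up and 4 down when adjusted over the list alone, camera adjusted p = 0.463). Gp5, a platelet glycoprotein gene, rose by 2.95 ± 0.28, and the list median of 0.373 was -0.092 without leukemia 2.

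**Figure D1:**
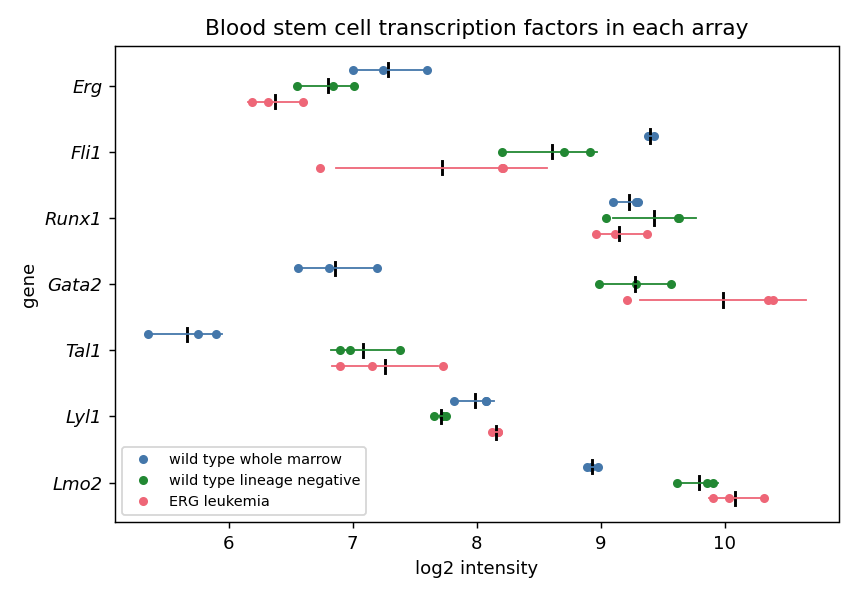
Log2 intensity of the 7 heptad genes on each array, by group, where points are arrays, black ticks are group means and horizontal lines span the mean ± SD. Gata2 lies at a mean of 6.85 in whole marrow and 9.99 in the leukemias, and Erg at 7.29 and 6.37.

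Signalling genes changed singly. Pim1, a survival kinase gene, rose 1.9-fold (0.93 ± 0.25, limma adjusted p = 0.0262) from a mean intensity of 267.3 to 507.7. This call was lost after cyclic loess (0.74), with only the 2 groups compared (0.93), and without leukemia 2 (0.83) or 3 (0.74) or whole marrow array 1 (0.79) or 3 (0.85). In the kinase and survival oncogene list, which is not independent of the study, Pim1, Stat5a, Myc, Cdk4 and Cdk6 rose and Braf, Mcl1, Syk and Igf1r fell among 23 measured (5 and 6 when adjusted over the list alone, camera adjusted p = 0.982). Myc rose by 1.41 ± 0.11 (adjusted p = 0.000422) and Syk changed by -1.76 ± 0.37. That list's median was 0.03 and its mean -0.025, the median was negative after both scalings and without whole marrow array 3 or leukemia 1 or 2, and 3 members rose after cyclic loess or without whole marrow array 1 or 3. Among 16 MAPK feedback genes Spred2 and Epha4 rose and Dusp6 (-1.81 ± 0.22), Spry2 and Phlda1 fell, also when adjusted over the list alone (camera adjusted p = 0.305). Epha4 rose by 0.92 ± 0.16. Of 20 p53 targets 6 rose, led by Zmat3 (at least 2.84-fold), and 5 fell, namely Trp53inp1 (-1.48 ± 0.22), Mdm2, Fas, Btg2 and Tnfrsf10b, also when adjusted over the list alone (camera adjusted p = 0.392).

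The remaining lists moved little or rested on few genes. Of 29 monocyte, macrophage and dendritic cell genes 6 fell and 0 rose, also when adjusted over the list alone, with the adhesion molecule gene Vcam1 at -1.57 ± 0.28 and Cd209a at -1.53 ± 0.27. The monocyte list had a camera adjusted p of 0.14, and without leukemia 2, which stood far below the other leukemias in several of these genes, 6 members rose. Its median of -0.068 turned to 0.18 without leukemia 2 and to 0.027 without whole marrow array 2, and camera's adjusted p was 0.0114 without leukemia 1, 0.0317 without leukemia 3 and 0.038 among bright genes alone. In the plasma cell list Irf4 (-2.33 ± 0.56) and Mzb1 (-1.41 ± 0.38) fell among 11, also when adjusted over the list alone (camera adjusted p = 0.0358, and adjusted p = 0.575 with an estimated correlation). With leukemia 3 left out 4 plasma cell genes fell. The camera call was lost without whole marrow array 1 (0.116) or leukemia 2 (0.376), Irf4 was lost without leukemia 2 (-1.999), and Mzb1 without leukemia 1 (-1.34) or 2 (-1.12) or whole marrow array 1 (-1.39) or 3 (-1.20). Of 24 stroma, bone and endothelium genes Col1a2 and Mgp rose and Cxcl12, Kitl, Cdh5 and Vcam1 fell (2 and 6 when adjusted over the list alone, camera adjusted p = 0.061). The Mgp call (0.78 ± 0.23) was lost when any 1 array other than leukemia 2 or 3 was left out, at values from 0.762 to 0.834. It was also lost with only the 2 groups compared (0.783). Without any 1 of the wild type arrays 0 stroma genes rose and without leukemia 1 it was 1, while 1 fell without whole marrow array 1 and 2 fell without leukemia 1. The stroma list passed by camera without whole marrow array 2 (0.0369) or 3 (0.0477), lineage-negative pool 1 (0.0437) or 3 (0.0461) or leukemia 3 (0.0276). Of 17 glycolysis genes Pfkl, Aldoc, Tpi1, Pdk1 and Bnip3 rose and Hk2, Pkm and Slc16a3 fell, also when adjusted over the list alone (camera adjusted p = 0.509, median 0.081, mean -0.037). Of the falls 1 was left without whole marrow array 1 or 2, lineage-negative pool 3 or leukemia 1 or 2, 3 members rose without whole marrow array 3 or leukemia 1, and the median was negative in those last fits and after both scalings.

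Camera at its preset correlation placed 14 of the 23 lists past the threshold for leukemia against whole marrow, 9 for leukemia against lineage-negative marrow and 16 between the wild type groups. With an estimated correlation it placed 0, 0 and 0, with lowest adjusted p of 0.303, 0.204 and 0.275, while fry placed 15, 4 and 18. When the 6 leukemia and whole marrow arrays were divided otherwise, camera placed up to 16 lists past the threshold, so the statements above rest on the members and their own tests.

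**Figure D2:**
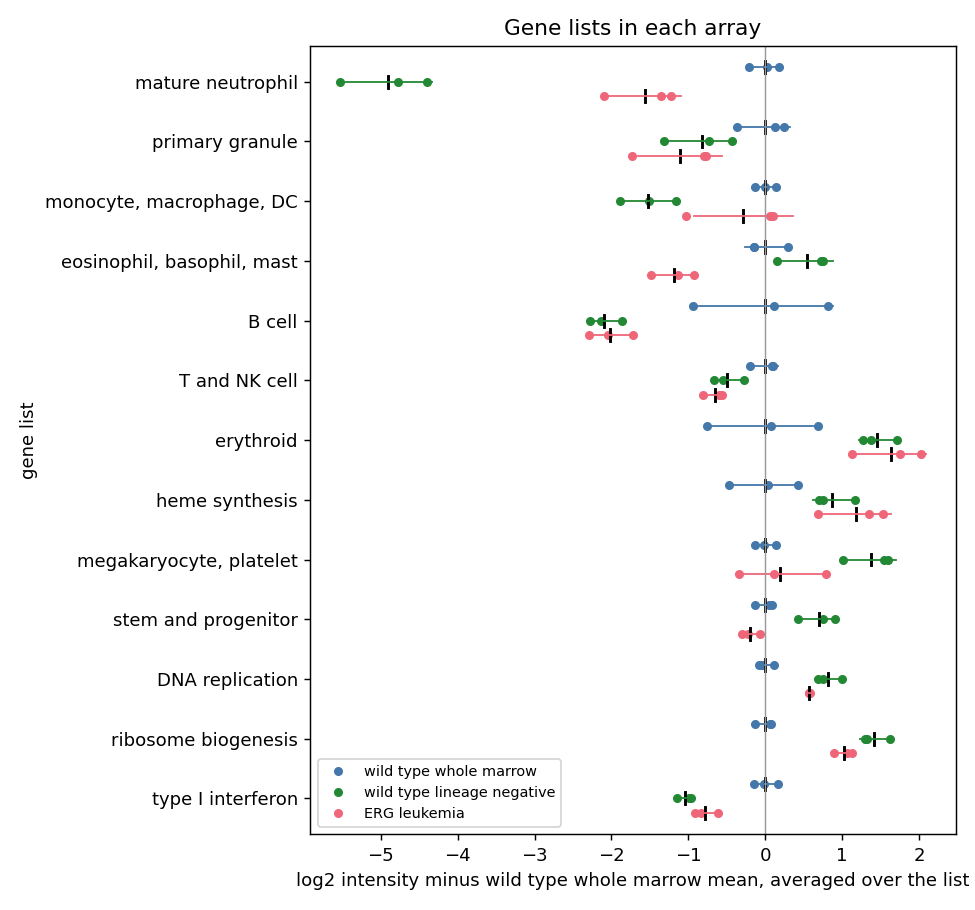
Mean over the members of each list of log2 intensity minus the wild type whole marrow mean, for each array, by group, with points for arrays, black ticks for group means and lines for the mean ± SD. Median log2 differences of the leukemias from whole marrow were 1.67 for erythroid genes and -2.11 for B cell genes.

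Against lineage-negative marrow, the immature reference, the leukemias had higher signal of mature neutrophil genes and lower signal of stem and progenitor, eosinophil, basophil and mast cell genes. Of 23 mature neutrophil genes 21 rose, with a median log2 difference of 3.85, while 15 of 27 stem and progenitor genes fell, with a median of -0.84. Mature cells had been removed from this reference. Against whole marrow the mature neutrophil median was -4.85 in lineage-negative marrow and -1.56 in the leukemias, and the stem and progenitor median 0.79 and -0.24. The neutrophil rise is thus set by that depletion, and the stem and progenitor fall cannot be parted from it. Erythroid and heme synthesis genes, higher than in whole marrow, had 0 of 22 and 0 of 11 members past the threshold by limma against this reference, where 4512 of all genes had an unadjusted p under 0.05. Without whole marrow array 2 or 3 or leukemia 1 there was 1 erythroid call, and heme synthesis had 2, 1 and 2 calls in those fits. Camera's adjusted p was 0.216 for erythroid genes (0.0225 without leukemia 1) and 0.203 for heme synthesis (0.0386 without lineage-negative pool 2 and 0.0159 without leukemia 1). B cell, T and NK cell and interferon lists, lower than in whole marrow, had few calls here. B cells had 1 of 25 genes up and 1 down, T and NK cells 0 of 28 and 2, and interferon targets 2 of 22 and 2. Adjusted over each list alone these were 1 and 1, 0 and 1, and 6 and 2. For these lists camera's adjusted p was 0.499, 0.216 and 0.216, and 0.0277 for T and NK cells without lineage-negative pool 2. In total 589 genes were higher and 1144 lower, 8.7% of those tested, and 27.9% of genes had groups whose arrays did not overlap, against 10% by chance. The share higher was 34% with the deposited values, 44% with 75th percentile centring (715 higher and 909 lower) and 44.9% after cyclic loess (719 and 881). The balance turned without leukemia 2, with 50.6% higher (827 and 808), and at a log2 size of at least 1, with 54.2%. Without lineage-negative pool 1, 2 or 3 the counts were 314, 334 and 268 higher and 490, 720 and 690 lower, and without leukemia 3, 607 were lower.

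The largest rises over lineage-negative marrow included those of the neutrophil granule genes Ltf, Mmp8 and Camp. Chil3, a chitinase-like protein gene of myeloid cells, rose 56.1-fold, from a mean intensity of 42.4 to 2381.0 (log2 difference 5.81 ± 0.34, limma adjusted p = 0.000153). The lactoferrin gene Ltf rose 31.9-fold (4.99 ± 0.39, adjusted p = 0.000566), Mmp8, neutrophil collagenase, 25.1-fold, Ifitm6 24.2-fold, Lrg1 at least 23.2-fold and the cathelicidin gene Camp 22.8-fold. Adjusted over the list alone, 22 mature neutrophil genes rose and 1 fell (camera adjusted p = 1.04e-27, and adjusted p = 0.204 with an estimated correlation). Of 29 monocyte, macrophage and dendritic cell genes 11 rose and 1, Zbtb46, fell (17 and 3 when adjusted over the list alone). The complement gene C1qb rose by at least 4.14 ± 0.54 and C1qc by at least 3.56 ± 0.59. For the monocyte list camera's adjusted p was 6.7e-09, with adjusted p = 0.454 with an estimated correlation. The number that rose was 7 without whole marrow array 1, lineage-negative pool 1 or 2 or leukemia 3, 6 without lineage-negative pool 3 and 18 without leukemia 2. The number that fell was 0 without whole marrow array 1 or 3, pool 3 or leukemia 2 or 3 and 2 without pool 2 or leukemia 1.

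Eosinophil, basophil and mast cell genes and some platelet genes were lower than in lineage-negative marrow. Ppbp changed by -5.08 ± 0.51 (limma adjusted p = 0.00127), Mcpt8 by -3.95 ± 0.48 (adjusted p = 0.00285), the eosinophil peroxidase gene Epx by -3.94 ± 0.35 (adjusted p = 0.000886), Timp3 by -3.88 ± 0.19 (adjusted p = 8.54e-05) and the platelet lipoxygenase gene Alox12 by -3.66 ± 0.42 (adjusted p = 0.00204). Eif2s3y, on the Y chromosome, was at least 15.9-fold lower (-3.99 ± 1.02, adjusted p = 0.0462). This call was lost after cyclic loess (-3.91) and without whole marrow array 1 (-3.99), lineage-negative pool 1 (-3.96), 2 (-3.93) or 3 (-4.10), or leukemia 1 (-4.03), 2 (-4.02) or 3 (-3.93). Of 19 eosinophil, basophil and mast cell genes 12 fell and 1, Ccr3, rose (13 and 1 when adjusted over the list alone), with a median of -2.11, and camera's adjusted p was 1.88e-10, with adjusted p = 0.307 with an estimated correlation. Ccr3 did not pass without any of lineage-negative pools 1, 2 and 3 or leukemias 1 and 2, each of which left 0 up. In the megakaryocyte and platelet list 6 of 20 genes fell and 1, Nfe2, rose (10 and 1 when adjusted over the list alone), with the platelet glycoprotein gene Gp9 9.74-fold lower (camera adjusted p = 0.000182, and adjusted p = 0.608 with an estimated correlation).

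Stem and progenitor genes fell in 15 of 27 cases and rose in 0 (20 and 1 when adjusted over the list alone). Meis1, a transcription factor of stem cells, changed by -2.61 ± 0.24 (limma adjusted p = 0.001) and the progenitor surface marker gene Cd34 by -2.50 ± 0.28 (adjusted p = 0.00197). Camera's adjusted p was 5.14e-12, with adjusted p = 0.204 with an estimated correlation. Kit, the stem cell factor receptor, was 4.31-fold lower (adjusted p = 0.000133) and Bcl2 2.72-fold lower (adjusted p = 0.0216), within a kinase and survival oncogene list, not independent of the study, in which Pim1 and Ccnd3 rose and Bcl2, Mycn, Kit and Cdk4 fell among 23 (3 and 6 when adjusted over the list alone). Bcl2 was lost without leukemia 3 (-1.496) or lineage-negative pool 1 (-1.24) or 3 (-1.42). Without lineage-negative pool 1 or 3 that list held 1 up and 2 down, without leukemia 3 it held 2 down, and camera's adjusted p of 0.169 became 0.0386 without lineage-negative pool 2. Pim1 rose 2.5-fold (1.32 ± 0.25, adjusted p = 0.0153), a call lost without lineage-negative pool 1 (1.33) or 3 (1.28). Of the heptad, Lyl1 rose (0.44 ± 0.09, adjusted p = 0.0171), a call lost without leukemia 3 (0.44) or lineage-negative pool 1 (0.46), 2 (0.41) or 3 (0.45).

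The other heptad genes did not pass against lineage-negative marrow. Their limma log2 differences were -0.43 ± 0.18 for Erg (adjusted p = 0.197), -0.89 ± 0.37 for Fli1 (adjusted p = 0.193), -0.28 ± 0.17 for Runx1 (adjusted p = 0.399), 0.71 ± 0.32 for Gata2 (adjusted p = 0.235), 0.18 ± 0.23 for Tal1 (adjusted p = 0.762) and 0.29 ± 0.12 for Lmo2 (adjusted p = 0.188). Without leukemia 3, Gata2 passed at 1.09, and with array weights Erg passed at -0.48. Ribosome biogenesis genes, of which all 29 rose against whole marrow, fell here in 5 of 29 cases, namely Rrs1, Nop16, Nolc1, Dkc1 and Utp20 (12 fell when adjusted over the list alone, median -0.362, camera adjusted p = 4.3e-09, and adjusted p = 0.454 with an estimated correlation). Their count was 2 without whole marrow array 1, 3 without whole marrow array 3, 1 without lineage-negative pool 1 or 2, 2 without pool 3, 3 without leukemia 2 and 0 without leukemia 3. Of 31 DNA replication genes Mcm10, Rfc3 and Ccne1 fell (6 when adjusted over the list alone, camera adjusted p = 3.29e-05, and adjusted p = 0.608 with an estimated correlation). That count was 0 without lineage-negative pool 2 or 3 or leukemia 3 and 1 without pool 1 or leukemia 1 or 2. Among MAPK feedback genes Spred1 (-1.43 ± 0.13), Spred2 and Spry2 fell and Epha4 (0.94 ± 0.16) rose (1 up and 5 down when adjusted over the list alone, camera adjusted p = 0.0258, and adjusted p = 0.454 with an estimated correlation), and camera's call was lost without lineage-negative pool 1 (0.0841) or 3 (0.0799) or leukemia 1 (0.095) and among bright genes alone (0.114). Among glycolysis genes Slc16a3, a lactate exporter (1.65 ± 0.17), Bnip3 (1.02 ± 0.10) and Aldoc rose and Pdk1 fell (6 up and 1 down when adjusted over the list alone, camera adjusted p = 0.0062, and adjusted p = 0.627 with an estimated correlation). The Pdk1 call was lost without any 1 array, and camera's without leukemia 1 (0.0561).

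In lineage-negative marrow, most mature neutrophil, B cell and monocyte genes were lower than in whole marrow, and most stem, erythroid, megakaryocyte, replication and ribosome genes were higher. All 23 mature neutrophil genes fell, with a median of -4.85, and all 29 ribosome biogenesis genes rose, with a median of 1.37. By limma, 4328 genes were higher and 2587 lower in lineage-negative marrow, 34.7% of those tested, and 50% of genes had groups whose arrays did not overlap, against 10% by chance. The share higher was 62.6%, against 50.3% with 75th percentile centring (3342 and 3299) and 51.2% after cyclic loess (3253 and 3095), and 52.6% at a log2 size of at least 1. The median log2 difference over all genes was -0.035 with the deposited values and -0.159 with 75th percentile centring.

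The largest falls in lineage-negative marrow included those of the neutrophil genes Ltf, Ly6g and Mmp9. Chil3 changed by -6.36 ± 0.34 (limma adjusted p = 3.09e-05), Ltf by -6.30 ± 0.39 (adjusted p = 4.61e-05), Slfn4 by -6.22 ± 0.51 (adjusted p = 8.31e-05), the neutrophil surface marker gene Ly6g by -6.20 ± 0.63 (adjusted p = 0.000176), the gelatinase gene Mmp9 by -6.11 ± 0.34 and Il1f9 by -6.07 ± 0.47. The mature neutrophil list had a camera adjusted p of 2.75e-19, with adjusted p = 0.275 with an estimated correlation. Of 25 B cell genes 18 fell and 0 rose (20 fell when adjusted over the list alone), with Ebf1 at least 15.5-fold and Ms4a1, which encodes CD20, at least 13.9-fold lower (camera adjusted p = 2.5e-08, and adjusted p = 0.423 with an estimated correlation). Of 29 monocyte, macrophage and dendritic cell genes 19 fell and 2, Flt3 and Zbtb46, rose (20 and 2 when adjusted over the list alone). C1qb changed by -3.19 ± 0.54, a lower bound in size, and the lysozyme gene Lyz2 by -3.12 ± 0.38. For the monocyte list camera's adjusted p was 2.05e-06, with adjusted p = 0.423 with an estimated correlation. In it 12 fell without whole marrow array 2 and 11 without lineage-negative pool 2. In that list 1 rose without whole marrow array 2 or 3 or lineage-negative pool 1 or 3. Interferon targets fell in 15 of 22 cases, also when adjusted over the list alone, led by Oas2, at least 9.41-fold lower, and Oas3, 4.93-fold lower (camera adjusted p = 3.83e-06, and adjusted p = 0.275 with an estimated correlation), and 9 fell without whole marrow array 1 and 8 without lineage-negative pool 3. Erg (-0.48 ± 0.18, adjusted p = 0.0695) and Pim1 (-0.40 ± 0.25, adjusted p = 0.267) did not pass. Erg passed with 75th percentile centring (-0.61), after cyclic loess (-0.74), among bright genes alone (-0.48) and without whole marrow array 3 (-0.62).

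Rises in lineage-negative marrow were led by Atp1b2 (2.91 ± 0.36, limma adjusted p = 0.000392), Tspo2, active in red cell precursors (2.80 ± 0.31, adjusted p = 0.00027), Ces2g (2.65 ± 0.36), Gata1 (2.64 ± 0.45), Clca3a1 (2.61 ± 0.31) and Timp3 (2.60 ± 0.19). Of 22 erythroid genes 17 rose and 0 fell (18 rose when adjusted over the list alone), with the erythropoietin receptor gene Epor 4.32-fold higher. Of 20 megakaryocyte and platelet genes 14 rose and 1, Cd9, fell (14 and 2 when adjusted over the list alone), with F2rl2 at 2.59 ± 0.53 and Gp5 at 2.43 ± 0.28. In that list 0 fell without whole marrow array 1 or 2, lineage-negative pool 2 or 3 or leukemia 2 or 3, and 2 without whole marrow array 3. Of 27 stem and progenitor genes 16 rose and 2, Prom1 and Satb1, fell (18 and 2 when adjusted over the list alone), with Angpt1 at 2.18 ± 0.33 and Prom1 at -2.47 ± 0.39, and 1 fell without whole marrow array 1 or 3 or lineage-negative pool 2 or 3. Camera's adjusted p was 2.7e-06, 0.000163 and 5.69e-05 for these lists in that order, with adjusted p = 0.503, adjusted p = 0.493 and adjusted p = 0.423 with an estimated correlation. In the eosinophil, basophil and mast cell list 7 of 19 genes rose, among them Kit, 3.42-fold higher, and 2, Hdc and Ccr3, fell (8 and 2 when adjusted over the list alone). Camera's adjusted p for that list was 0.115, and it was 0.0283 without whole marrow array 1 and 0.0142 without lineage-negative pool 2. DNA replication genes rose in 29 of 31 cases (29 also when adjusted over the list alone), led by the cyclin gene Ccne1 (1.42 ± 0.18) and Pole (1.18 ± 0.14), with camera's adjusted p at 1.64e-13, and adjusted p = 0.389 with an estimated correlation. For ribosome biogenesis, where Cad rose 4.37-fold and Rrp9 3.67-fold, camera's adjusted p was 3.03e-18, with adjusted p = 0.275 with an estimated correlation.

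Across genes, the leukemias lay part of the way from whole to lineage-negative marrow. Over 19938 genes, the difference of the leukemias from whole marrow rose by 0.59 for each log2 unit of difference between lineage-negative and whole marrow, with Pearson's r at 0.777 and Spearman's rho at 0.758. Genes are not independent replicates, and both differences share the whole marrow arrays. Simulated data with no effects gave an r of 0.502 and a covariance of 0.013, against an observed covariance of 0.302. A corrected slope took the noise of the shared arrays off the covariance, and the noise of both wild type means off the variance of their difference. The first step lowers the slope and the second raises it, and together they gave 0.594. Of the 4328 genes higher in lineage-negative than in whole marrow, 2521 (58.2%) also rose in the leukemias and 43 fell. Of the 2587 lower ones, 1522 (58.8%) also fell and 4, named after their values were seen, rose (Apoc1, Bnip3, Ms4a8a and Wdfy3). Independent lists of these sizes would share 629.7 and 256.9 genes, which leaves out the shared arrays. The highest overlap in 20 simulations with no effects was 0, a value that leaves out the effects, without which almost no gene is called, and so does not measure what the shared arrays add. In a check added after results were seen, 1 whole marrow array served one comparison and 2 the other, in all 6 ways. The r then ran from 0.647 to 0.744, and 805 to 1763 genes were higher and 491 to 902 lower in both, against at most 405.6 and 174.6 for independent lists.

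**Figure D3:**
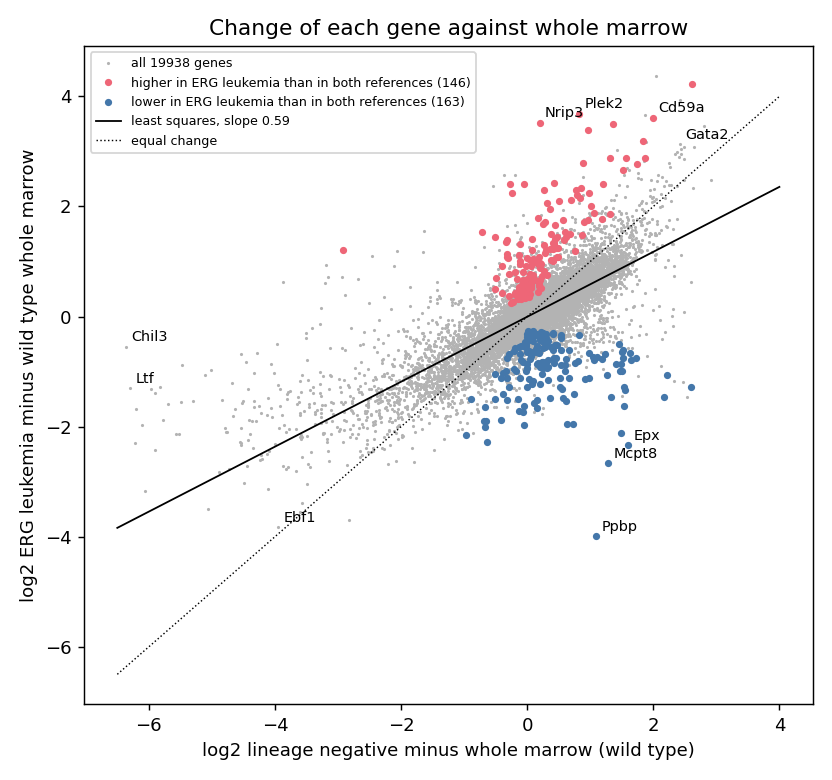
Log2 difference of the leukemias from whole marrow (vertical axis) against log2 difference of lineage-negative from whole marrow (horizontal axis), with 1 point per gene over 19938 genes. The fitted slope is 0.59 and r is 0.777.

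A smaller set of genes stood outside both references. In the leukemias 146 genes were higher and 163 lower than in whole and in lineage-negative marrow alike, against 85.7 and 113.6 for independent lists. In 20 simulations with no effects the highest count was 0, which follows from there being almost no calls and does not measure what the shared arrays add. The comparisons share the leukemia arrays. With these split 1 and 2 between the comparisons, a check added after results were seen, 13 to 182 genes were higher and 17 to 101 lower than both. These counts were above those for independent lists in 4 and 6 of 6 splits, so part of the excess may come from the shared arrays. Another 297 genes lay above whole and below lineage-negative marrow, and 223 below whole and above lineage-negative marrow. Among genes chosen after their values were seen, Nrip3 rose from log2 means of 4.27 and 4.46, both below the median of all probe sets (5.063), to 7.79, at least 3.52 ± 0.20 above whole and 3.33 ± 0.20 above lineage-negative marrow. Ndrg2 rose by 3.39 ± 0.54 and 2.42 ± 0.54, the fatty acid transporter gene Cd36 by 2.41 ± 0.42 and 2.68 ± 0.42, and the hemoglobin theta gene Hbq1b by 2.40 ± 0.28 and 2.45 ± 0.28. Lower than in both were Ppbp, Mcpt8, Epx and, also chosen after their values were seen, the mast cell protease gene Prss34 (-2.12 ± 0.39 and -3.60 ± 0.39) and the eosinophil granule gene Prg2 (-1.95 ± 0.30 and -2.68 ± 0.30).

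Eosinophil, basophil and mast cell genes were over-represented among those lower than both references. Of 19 measured, 8 were lower, namely Epx, Prg2, Prg3, Ear6, Ms4a2, Fcer1a, Mcpt8 and Prss34 (Fisher's exact test, adjusted p = 2.7e-11), and 8 to 10 were lower when any 1 array was left out. Megakaryocyte genes had 3 of 20 there (Ppbp, Itgb3 and Gp9, adjusted p = 0.00635), and stem and progenitor genes 3 of 27 (Cd34, Sox4 and Satb1, adjusted p = 0.0104). Fisher's test treats genes as independent, while camera estimated correlations of 0.374, 0.515 and 0.204 within these lists in that order. Its p-values are therefore too small, and the counts serve as a description. The stem and progenitor count was 1 without whole marrow array 1 or 3, lineage-negative pool 3 or leukemia 2 or 3, 2 without whole marrow array 2, 4 without leukemia 1 and 6 without pool 2. No list was over-represented among genes higher than both, where the lowest adjusted p was 0.107. The number higher was 80 without whole marrow array 1 and 39, 96 and 45 without lineage-negative pools 1, 2 and 3. The number lower was 76 and 96 without whole marrow arrays 1 and 3, 102 and 80 without pools 1 and 3, and 87 and 100 without leukemias 2 and 3.

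Leukemias differed more among themselves than the wild type arrays did in some genes. An SD over 1 was seen in 164 genes in the leukemias, 69 in whole marrow and 15 in the lineage-negative pools, each of which averages 3 mice. Leukemia 2 was farthest from the median of the leukemias in 108 of the 164 genes, and the lower one in 94. Of the measured members, 6 of 29 monocyte, macrophage and dendritic cell genes, 5 of 20 megakaryocyte genes and 3 of 23 mature neutrophil genes were among the 164. Leukemia 2 was the lowest in each of these monocyte and neutrophil genes and the highest in each of the megakaryocyte genes, which were Pf4 (7.37, 10.08 and 9.12 in leukemias 1, 2 and 3), Ppbp, Itga2b, Treml1 and F2rl2. Genes chosen after their values were seen include the lectin receptor gene Cd72, at log2 9.13, 5.08 and 9.54 in leukemias 1, 2 and 3, the monocyte receptor gene Cd300e, at 8.60, 4.66 and 9.11, the Fc receptor gene Fcgr4, at 10.13, 6.28 and 10.53, and the dendritic cell integrin gene Itgax, at 7.08, 4.56 and 7.37.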

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

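Of the tests below, those on the Erg probe set and on male RNA in all lineage-negative pools were chosen after results were seen. Leaving out each array was planned before the data were seen, and whole marrow array 2 was singled out after its Y-linked signal was seen. Array probe sets left out of the gene tests also held signal. Of 5443 probe sets with no gene name, 580 passed the threshold between the leukemias and whole marrow and 120 between the leukemias and lineage-negative marrow. Of 1621 probe sets with several names, 285 and 53 passed in that order.

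The numbers of changed genes and lists were compared with all 10 divisions of the 6 arrays of a comparison into 3 and 3, which are too few for a share under 0.05. Counting the real one, 1 division reached the real count of genes in each comparison, with 4881 against a highest other of 1 for leukemia and whole marrow, 1733 against 0 for leukemia and lineage-negative marrow, and 6915 against 0 between the wild type groups. For lists past the threshold by camera, 4 divisions reached the real 14 (highest other 16), 7 reached the real 9 (highest other 13) and 1 reached the real 16 (highest other 14).

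The 309 genes outside both references were weighed against 3 explanations. Of 100 groupings of the 9 arrays into 3 groups of 3, 5 reached 309, with a highest other of 3465, so by the share fixed beforehand this count alone does not exclude chance. The 4 others that reached it each put a whole wild type group in the place of the leukemias, which points to the structure of the samples, and all the remaining groupings gave at most 3. A mixture of the whole marrow and lineage-negative marrow profiles lies between them for every gene, so only noise can put genes outside both. It gave at most 5 such genes in 20 simulations, with noise drawn apart for each gene and array. Real genes vary together, with a correlation estimated by camera at 0.881 within the erythroid list, and this could put more genes outside both. The simulations thus argue only against a mixture with cell proportions fixed within each profile and with noise that is independent between genes. Other proportions of ordinary marrow cells stay open, as does another cell population. Male RNA in whole marrow array 2 was tested by leaving that array out, and the median share of the log2 change that was kept was 1.038, but the genes had been chosen with it included, so this share says nothing about male RNA. In that fit 230 of the 309 passed again, and 129 genes in all were higher and 170 lower than both references, against 146 and 163 with it. The number of lineage-negative arrays without Y-linked signal was 0, and male RNA stays open.

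The lower signal of the mouse Erg probe set in the leukemias than in whole marrow was weighed against 2 explanations. Fewer mature neutrophils could lower it, and lineage-negative marrow would then have at least as large a fall. Its mature neutrophil median against whole marrow was -4.85, against -1.56 in the leukemias, yet its fall in Erg was smaller than theirs. The difference in Erg between the leukemias and lineage-negative marrow did not pass (-0.43, limma adjusted p = 0.197) but passed with array weights (-0.48), so the data do not decide. The transgene's transcript may not be read by the mouse probes, and with 1 probe set naming Erg this could not be tested.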

How the results depend on the processing

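The added gene families and the split of shared arrays were chosen after the data were seen, and the other alternatives, leaving out each array among them, before. Of 163 pairs of a named gene and a comparison, 153 passed the threshold, 123 of these did so in the same direction under every alternative run on single genes, and 0 reversed. The log2 size of at least 1 and the separate probe sets were run on counts alone. With an estimated correlation camera placed 0 lists past the threshold in each of the 3 comparisons, where the preset correlation gave 14, 9 and 16, and fry placed 4 for leukemia against lineage-negative marrow. There fry ended the calls of DNA replication (fry adjusted p = 0.124), glycolysis (0.175), ribosome biogenesis, monocytes and megakaryocytes (0.0506 each). Against whole marrow it ended that of plasma cells (0.232) and added the heptad (0.00269) and stroma (0.0419). Between the wild type groups it ended primary granules (0.143) and added the heptad (0.00516), kinase oncogenes (0.00883) and MAPK feedback (0.0489). Array weights gave 1388 genes higher and 2001 lower for leukemia against lineage-negative marrow, 337 higher and 311 lower than both references, and a slope of 0.551. The cause was not tested. By camera, bright genes alone or cyclic loess also ended the calls of cholesterol synthesis, stroma, heme synthesis and mitosis between the wild type groups, made glycolysis pass there, and made p53 targets and mitosis pass for leukemia against lineage-negative marrow. A required log2 size of at least 1, which by construction leaves fewer genes, gave 616 higher and 795 lower for leukemia against whole marrow, 299 and 253 against lineage-negative marrow, 1201 and 1081 between the wild type groups, and 49 and 48 against both references.

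When each array was left out in turn, which by construction leaves fewer samples, genes higher in leukemia than whole marrow ran from 2350 to 2835 and genes lower from 1248 to 1915. Against lineage-negative marrow they ran from 268 to 827 and from 490 to 1174, between the wild type groups from 3611 to 4462 and from 1863 to 2748, and against both references from 39 to 194 and from 76 to 198. Lists past the threshold ran from 13 to 16, from 8 to 16 and from 14 to 16 in the order used above. The slope ran from 0.522 without leukemia 2 to 0.632 without leukemia 3. With only the 2 groups compared, 2414 genes were higher and 1532 lower for leukemia against whole marrow. Against lineage-negative marrow these were 418 and 806, and between the wild type groups 4487 and 2658. With the replicate number as a replicate block, lineage-negative against whole marrow gave 4346 genes higher and 2547 lower. These numbers pair different mice, and arrays with the same number correlated in their deviations at r of 0.312, -0.009 and -0.009. Signal near background limits dim genes, since 55.2% of genes had a group mean above the median intensity of 33.4.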

Other observations

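The gene families and genes in this part were chosen after results were seen. The camera values are adjusted over the 12 families tested. Genes of protein synthesis beyond the ribosome biogenesis list were higher in the leukemias than in whole marrow, and some were lower than in lineage-negative marrow. Of 30 aminoacyl-tRNA synthetase genes, whose products load amino acids onto tRNA, 24 rose and 0 fell by limma (25 and 0 when adjusted over the family alone), with Iars2 at 1.44 ± 0.16 and Hars at 1.42 ± 0.18. The camera test gave them an adjusted p of 2.95e-15, with adjusted p = 0.242 with an estimated correlation. Of 77 mitochondrial ribosomal protein genes 45 rose and 1, Mrpl33, fell (55 and 1 when adjusted over the family alone), with Mrpl52 at 1.45 ± 0.13 (camera adjusted p = 2.9e-17, and adjusted p = 0.242 with an estimated correlation). The Mrpl33 call was lost without whole marrow array 1 or 2, any 1 of the lineage-negative pools, or leukemia 1 or 2. Of 39 proteasome genes 19 rose and 0 fell, and 11 rose after cyclic loess, with Psmd3 at 1.23 ± 0.12 (camera adjusted p = 2.68e-09, and adjusted p = 0.242 with an estimated correlation). Against lineage-negative marrow 0 synthetase genes rose and 4 fell, namely Ears2, Rars2, Wars2 and Yars2 (7 fell when adjusted over the family alone, camera adjusted p = 0.000657, and adjusted p = 0.377 with an estimated correlation). That count was 0 without lineage-negative pool 1, 2 without pool 2 or 3 or leukemia 2, and 1 without leukemia 3. Of the mitochondrial ribosomal protein genes 0 rose and 9 fell there (18 fell when adjusted over the family alone, camera adjusted p = 2.75e-09, and adjusted p = 0.377 with an estimated correlation), and 3, 5 and 4 fell without pool 1, pool 2 and leukemia 3.

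Schlafen and Toll-like receptor genes were examined as families of innate immunity. Of 9 Schlafen genes, which are induced in myeloid and T cells, Slfn1, Slfn2, Slfn4, Slfn5 and Slfn8 were lower in the leukemias than in whole marrow (6 when adjusted over the family alone, camera adjusted p = 0.000223, and adjusted p = 0.242 with an estimated correlation). Against lineage-negative marrow Slfn1 (3.38 ± 0.27), Slfn2, Slfn4 and Slfn5 were higher and Slfn9 (-0.73 ± 0.19) was lower, with a median of -0.011 and a mean of 1.064 (4 and 1 when adjusted over the family alone, camera adjusted p = 0.027, and adjusted p = 0.377 with an estimated correlation). The Slfn9 call was lost after both scalings and without whole marrow array 1, any 1 of the lineage-negative pools, or leukemia 1 or 2. Of 10 Toll-like receptor genes Tlr13 (4.06 ± 0.36), Tlr8 (at least 3.20 ± 0.43), Tlr7 and Tlr2 were higher in the leukemias than in lineage-negative marrow (5 when adjusted over the family alone). Camera's adjusted p was 1.51e-05, with adjusted p = 0.35 with an estimated correlation, and 9 genes were higher without leukemia 2. Without lineage-negative pool 2, 1 was lower. Against whole marrow Tlr2 and Tlr6 were lower (4 when adjusted over the family alone, camera adjusted p = 0.00687, and adjusted p = 0.385 with an estimated correlation), and the count was 1 without any 1 of the whole marrow arrays and 4 without leukemia 3.

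The other 7 of the 12 families are given by the camera test, and the GTPases of immunity by their members too. Of 16 GTPase genes of immunity Gbp11, Gimap5, Gimap6, Gimap8 and Gimap9 were lower in the leukemias than in whole marrow (11 when adjusted over the family alone, camera adjusted p = 0.000223, and adjusted p = 0.274 with an estimated correlation). That count was 1 without whole marrow array 1, 11 without array 2, 2 without array 3 or leukemia 1, and 3 without lineage-negative pool 3 or leukemia 2. By camera, complex I genes (adjusted p = 5.12e-05) and mitochondrial carriers (0.037) stood higher against whole marrow, and C-type lectins (0.00221) and MHC class II genes (0.00527) lower. With an estimated correlation these were adjusted p = 0.262, adjusted p = 0.242, adjusted p = 0.242 and adjusted p = 0.274. Complex I had 10 genes up and 1 (Ndufb2) down of 35, carriers 13 up and 4 down of 46 (Slc25a24, Slc25a27, Slc25a29 and Slc25a45), lectins 1 (Clec4g) up and 9 down of 33, and MHC class II 2 down of 8 (H2-Ob and H2-Ea, with the limit on H2-Ea given above). With any 1 array left out these were 8 to 12 up and 0 to 1 down, 9 to 14 up and 2 to 4 down, 0 to 5 up and 3 to 9 down, and 0 to 3 down, with 3 lectins down without whole marrow array 1 and 5 up without leukemia 2. MS4A (0.295) and Hox A and B genes (0.264) did not pass there. Against lineage-negative marrow C-type lectins (0.000888) and MS4A genes (0.00173) stood higher and Hox A and B genes lower (0.0409), while complex I genes (0.0609), carriers (0.0609), MHC class II genes (0.334) and the GTPases (0.135) did not pass. The lectins had 8 up and 2 down (Clec1a and Clec1b), MS4A 5 up (Ms4a4a, Ms4a4c, Ms4a6d, Ms4a7 and Ms4a8a) and 1 (Ms4a2) down of 19, and Hox 5 down of 19 (Hoxa10, Hoxa4, Hoxa5, Hoxa6 and Hoxa7), each at adjusted p = 0.35 with an estimated correlation. With any 1 array left out 5 to 8 lectins and 3 to 7 MS4A genes were up and 1 to 4 Hox genes down. With an estimated correlation 0 of the 12 families passed in either comparison.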
